A study of Mus musculus with 4 samples.

How the data were processed

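RNA from 4 cultures of RAW 264.7 cells was extracted on RNeasy columns and 100 ng of total RNA was made into biotin-labelled cRNA for Affymetrix Mouse Gene 1.0 ST arrays, per the labels' protocols. The cultures carried a control vector or a miR-155 vector and were unstimulated or had 72 h of RANKL and M-CSF. The series text names 20 ng/ml, without saying whether this holds for each cytokine, and calls the control cells wild-type where the sample descriptions give a control vector. The groups follow the sample descriptions and titles. Each group has 1 array. Nothing pairs or repeats cultures.

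The deposited values are log2 expression values, 1 per probe set and array. RMA (background correction, quantile normalization and probe summary) and the software Partek are named in the submitters' processing notes; versions and the genome build are not given in the sources used here. The distributions of the 4 columns were nearly equal: their sorted values differed by at most 0.218 and by a median of 0.0637 (log2), and the array medians lay between 4.58 and 4.62. Quantile normalization of this kind forces equal distributions, so a change in total RNA per cell is not visible in these values. Arrays give no read depth. The number of arrays limits the precision, and no detection calls were used.

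The platform annotation named 21789 of 35557 probe sets with 1 gene symbol, 1621 with several and 12147 with none. Of the single-symbol probe sets, 21698 had their gene ID in a table of RefSeq genes (assembly GRCm38.p6), and 0 symbols changed. No coordinates are given, since the build of the annotation was not given in the sources used here. The probe set with the highest mean stood for each of the 19938 genes, 999 of which had more than 1. The floor was the 95th percentile of all values of 1212 olfactory and vomeronasal receptor probe sets, 4.25, and a gene counted as above it when its highest value over the 4 arrays exceeded it. The 95th percentile of the absolute log2 difference of these probe sets served as the noise reference of each comparison. To see whether 10 bins of mean expression can reveal an intensity-dependent bias, the values of the stimulated control array were drawn toward their median by a factor of 2, and quantile normalized again. Directions at equal intensity were counted in 100 bins of the unstimulated miR-155 array, which is outside that comparison, and again for a simulated bias with the noise of the receptor probe sets. The noise reference describes dim probe sets and is no replicate error. Where 1 of 2 values lay below the floor, the fold is given as a bound, the brighter value against the floor.

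Differences of log2 values were taken between the stimulated and unstimulated array of each vector, between the vectors in each state, and between the stimulation responses, and counted past 2-fold. For each of 23 gene lists the median difference of members above the floor was given with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins, which describes these arrays and is no p-value. Members past 1.5-fold were counted. The lists, the floor, the comparisons, the naming rule and the alternatives below, but for 2, were set before the data were examined. limma 3.58.1 (lmFit and eBayes, R 4.3.3) fitted stimulation and vector as additive terms over the 4 arrays, with Benjamini-Hochberg adjustment at 0.05 over the 13561 genes and, for each list, over the list alone. Its only residual degree of freedom is the interaction of the 2 terms, so its error is not the spread of replicate cultures, and it has little power for genes whose response differs between the vectors. On simulated data with additive changes and a noise SD of 0.2 over 13561 genes, the limma step recovered 96% of 50 genes changed by 1 (log2) and 100% of those changed by 2, 3 or 4, for stimulation and for miR-155. False calls numbered 5 for stimulation and 9 for miR-155. The simulated data held no interaction, while on these arrays the difference of the responses had an SD of 0.695. The recovery therefore does not give the power on these arrays. In a simulation of 100 lists of 25 genes with no shift, 5 fell outside the 2.5 to 97.5 percentiles, and 100 of 100 lists shifted by 0.3 were found. Its genes varied independently of each other. It therefore does not give how often lists whose members vary together fall outside that range. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

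The named genes are 20 preset ones; the 10 highest and 10 lowest by mean difference among genes past 2-fold in both vectors (stimulation), or past 1.5-fold in both states (miR-155); the 5 highest and 5 lowest for the difference of the responses; and up to 4 members of each list with the largest absolute difference in a comparison. Adam8 and Id2, genes with opposite directions (Atrx, Clec10a, Gda, Hmgn5, Hpgds, Igf1 and Pmp22), and Tfeb, Tfe3, Fnip1, Flcn and Rab27a were added after their values were seen, as were some list members given outside the comparison in which they rank among those 4. Unnamed probe sets, probe sets with several symbols and predicted genes were not named. Alternatives were renewed quantile normalization, median centring, no filter or a stricter filter (mean above the median of all probe sets), the mean over the probe sets of a gene, 1.5-fold and 3-fold thresholds, limma with an intensity trend or robust, rank correlation and the list mean. Removal of the median of each expression bin, and values below the floor set to the floor, were added after the data were examined. The planned comparison of genes with and without miR-155 seed sites was not run, because no transcript sequences were used here, and the list of reported targets stands alone. Several list members without a single-symbol probe set were left out, which leaves 556 of 594 list memberships.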

Results

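Gene expression was measured in RAW 264.7 cells, a mouse macrophage-like line that turns into multinucleated, bone-resorbing osteoclasts when given RANKL (the osteoclast-inducing ligand) together with M-CSF (a macrophage growth factor). Cells carried either a control vector or a vector that mis-expresses the microRNA miR-155, and RNA was taken before or after 72 h with both cytokines. The comparisons address how miR-155 bears on osteoclast differentiation. Each of the 4 groups has 1 array, so no difference between 2 arrays has a replicate check or a p-value, and the number of arrays limits the precision of every value. Of 19938 genes on the array, 13561 lay above a floor of 4.25 on the log2 scale, set from olfactory and vomeronasal receptor probe sets. Those receptor probe sets also served as a noise reference: 95% of them differed by less than 0.48 (log2) between the control arrays with and without stimulation, 0.41 between the miR-155 arrays, 0.37 between the unstimulated arrays and 0.47 between the stimulated arrays. Across genes above the floor, the stimulated control array stood apart. Its Pearson correlation was 0.916 with the unstimulated control array, 0.937 with the stimulated miR-155 array and 0.908 with the unstimulated miR-155 array, whereas the other 3 pairs of arrays reached 0.982 to 0.989.

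In cells with the control vector, 72 h of RANKL and M-CSF came with a large osteoclast programme. All but 1 of the 27 osteoclast markers were at least 1.5-fold higher, with a median log2 difference of 3.53, or 11.5-fold. Mmp9, a matrix metalloproteinase, was 129-fold higher (log2 7.02). Atp6v0d2, a subunit of the proton pump that also takes part in cell fusion, was 108-fold higher, Ctsk, the collagen-degrading cathepsin K, 103-fold, and Acp5, the tartrate-resistant acid phosphatase, 86.2-fold. Adam8, a membrane metalloproteinase, was the exception at -0.80. The V-ATPase subunits, which acidify lysosomes and the resorption space, had a median of 1.77, and 16 of 17 were at least 1.5-fold higher. The integrin subunits Itgb3 (3.61) and Itgav (3.53) and the kinase Src (4.36) led the list for the sealing zone and actin, whose median was 0.43, with 14 of 30 members higher and 1 lower. The cell fusion list had a median of 0.44 and a mean of 1.13, because Atp6v0d2 (6.75) and the membrane proteins required for fusion Ocstamp (5.28) and Dcstamp (4.54) stood far above the other members. The medians of these 4 lists all lay above the middle 95% of random lists matched on expression. The plot of preset genes shows the levels on each array.

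**Figure D1:**
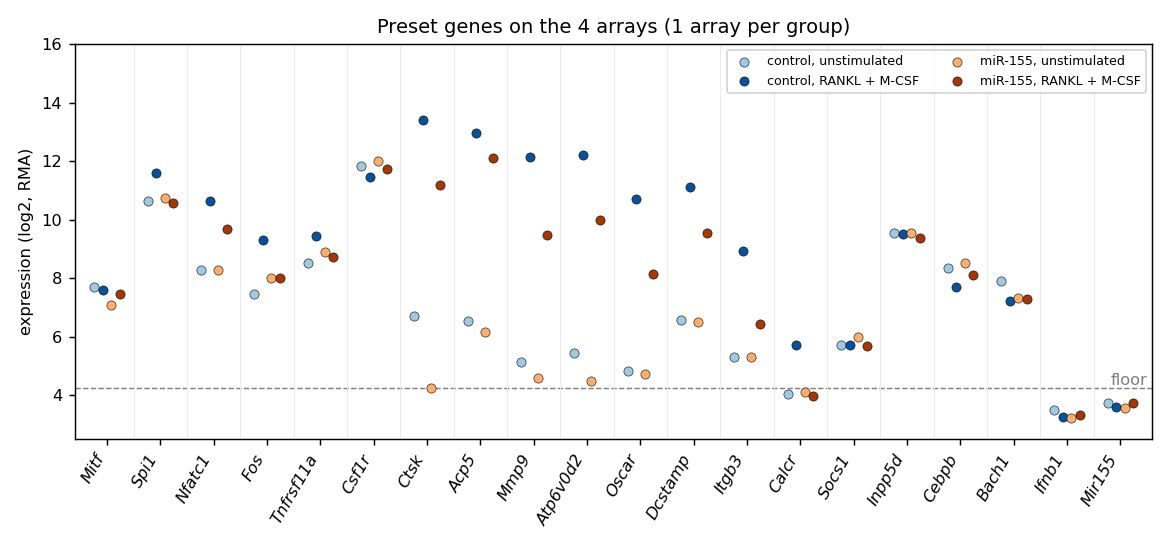
Log2 RMA expression of the preset genes, with 1 point per array and the floor of 4.25 as a dashed line. Ctsk, Acp5, Mmp9 and Atp6v0d2 reach 12.14 to 13.40 in the stimulated control array and 9.46 to 12.10 in the stimulated miR-155 array.

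Transcription factors tied to osteoclast differentiation were higher in the stimulated control cells by a median of 0.96, with 13 of 23 at least 1.5-fold higher and 4 lower. Prdm1, a repressor of macrophage genes, was at least 32.0-fold higher, Myc was higher by 4.04 and Fosl2 by 3.47. Nfatc1, the leading regulator of osteoclast genes, was higher by 2.34, Fos by 1.82 and Spi1, which encodes PU.1, by 0.96. Irf8, a restraint on osteoclast formation, was lower (-2.33). Mitf, a regulator of Ctsk and Acp5, stayed within the noise reference at -0.10. Among RANK and M-CSF signalling genes, the RANKL receptor gene Tnfrsf11a was higher by 0.91, the M-CSF receptor gene Csf1r stayed within the noise reference at -0.36, the kinase Syk was higher by 1.61, and the list median was 0.20, with 10 of 29 members at least 1.5-fold higher and 2 lower.

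Macrophage markers and genes of the cell cycle were lower in the stimulated control cells. The 22 macrophage markers above the floor had a median of -1.97, with 17 at least 1.5-fold lower and 1 higher. Cybb, the phagocyte NADPH oxidase subunit, was lower by 124-fold (-6.95), the fractalkine receptor Cx3cr1 had a difference of -5.32 and the adhesion receptor Adgre1 one of -4.38. The lysozyme genes Lyz1 (-6.39) and Lyz2 (-6.02) are near-identical copies, so their probe sets may not be separable. All 29 genes of the G2/M and mitosis list were at least 1.5-fold lower, with a median of -2.18, including the kinesin Kif11 (-3.07) and the proliferation marker Mki67 (-2.95). The G1/S and DNA replication list had a median of -1.89 and 28 of 29 members lower, led by the DNA primase subunit Prim1 (-2.71) and the helicase subunit Mcm3 (-2.50). Interferon-stimulated genes were lower as a list (median -1.03, 23 of 32 members at least 1.5-fold lower, none higher), with Usp18 at -2.32. None of 10000 matched random lists had a median as low as any of these 4. All 4 medians rest on the array that stood apart in the correlations between arrays.

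Several other lists were higher in the stimulated control cells. Oxidative phosphorylation genes had a median of 0.73, and 22 of 29 were at least 1.5-fold higher, among them Ppargc1b (1.59), a coactivator of mitochondrial biogenesis. Iron and heme genes had a median of 0.68, led by the iron importer Slc11a2 (1.48) and the transferrin receptor Tfrc (1.11). Cholesterol biosynthesis genes had a median of 0.39, p53 targets and cell cycle inhibitors 0.32, lysosome genes 0.29 and inflammatory cytokines and chemokines 0.31, the last inside the range of random lists without a filter on low values. The lysosome list split, with 12 of 27 members at least 1.5-fold higher, such as Glb1 (2.63), and 8 lower, such as Ctsl (-1.63). Among the inflammatory genes the interleukin 1 receptor antagonist Il1rn stood highest (3.53). The list of MHC class II and dendritic cell markers had a median of 0.51, with 5 of 11 members at least 1.5-fold higher, and was led by Cd80 (2.62), Itgax (2.59) and Cd83 (2.58), which encode a costimulatory ligand, an integrin and an activation marker. Glycolysis (-0.04), unfolded protein and stress response genes (0.04), T and B cell markers (-0.09), fibroblast and osteoblast markers (-0.09) and granulocyte and mast cell markers (0.10) lay within the middle 95% of random lists. So did genes reported elsewhere as miR-155 targets (-0.11), with 12 of 46 at least 1.5-fold lower and 6 higher. In total 1716 genes, or 12.7%, were past 2-fold, 777 higher and 939 lower, against 3 of 1212 receptor probe sets.

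In cells with the miR-155 vector the same treatment came with induction of osteoclast genes at smaller sizes and with smaller decreases than in control cells. Osteoclast markers had a median of 1.45, with 18 of 27 at least 1.5-fold higher and none lower. Ctsk was higher by 6.92 from a level of 4.26, next to the floor, Acp5 by 5.93, Atp6v0d2 by 5.52 and Mmp9 by 4.88. The membrane metalloproteinase Mmp14, higher by 3.65 in control cells, was not higher here (-0.23). The calcitonin receptor Calcr, at least 2.76-fold higher in control cells, lay below the floor in both miR-155 arrays. V-ATPase subunits had a median of 0.75. The osteoclast transcription factors had a median of -0.15 and a mean of 0.34, which differ in sign: Myc (2.85), Jdp2 (2.33), Prdm1 (2.05) and Nfatc1 (1.42) were higher, while Fos (0.00) and Spi1 (-0.20) were not. Macrophage markers had a median of -0.17, with 1 of 22 members at least 1.5-fold higher and 1 lower. The G2/M list stood at -0.09, inside the range of random lists, and the G1/S list at -0.19, below that range but inside it after renewed quantile normalization. Interferon-stimulated genes were lower by a median of -0.36 (11 of 32 at least 1.5-fold lower), led by Irf7 (-1.37). Lysosome genes (0.12) and oxidative phosphorylation genes (0.13) lay above the middle 95% of random lists.

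The remaining lists lay within the middle 95% of random lists in the miR-155 cells: RANK and M-CSF signalling -0.01, cell fusion -0.01 (mean 0.66, with Atp6v0d2 at 5.52, Ocstamp at 3.18 and Dcstamp at 3.06), sealing zone and actin -0.00, inflammatory genes -0.07, MHC class II and dendritic cell markers -0.01, p53 targets 0.02, cholesterol biosynthesis 0.00, glycolysis -0.10, iron and heme 0.08, and stress response 0.02. T and B cell (-0.00), fibroblast and osteoblast (0.07) and granulocyte and mast cell markers (-0.02) did so too, as did the reported miR-155 targets (-0.13, the 3.14 percentile). In all, 181 genes were past 2-fold, 156 higher and 25 lower, and no receptor probe set was. This balance depends on the threshold: at 1.5-fold 465 genes were higher and 506 lower, against 1673 and 2053 in control cells.

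The stimulation responses of the 2 vectors share no array and can be set against each other. Of the 156 genes more than 2-fold higher in miR-155 cells, 142 were also more than 2-fold higher in control cells, against 8.94 for independent lists. Of the 25 lower genes, 12 were shared, against 1.73. The 777 genes higher in control cells had a median of 0.42 in miR-155 cells and 687 of them (88.4%) had the same sign. The 939 lower genes had a median of -0.17 and 641 (68.3%) had the same sign. Across genes, which are not independent replicates, the responses correlated with a Pearson r of 0.47 and a Spearman rho of 0.28, as the plot of the responses shows.

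**Figure D2:**
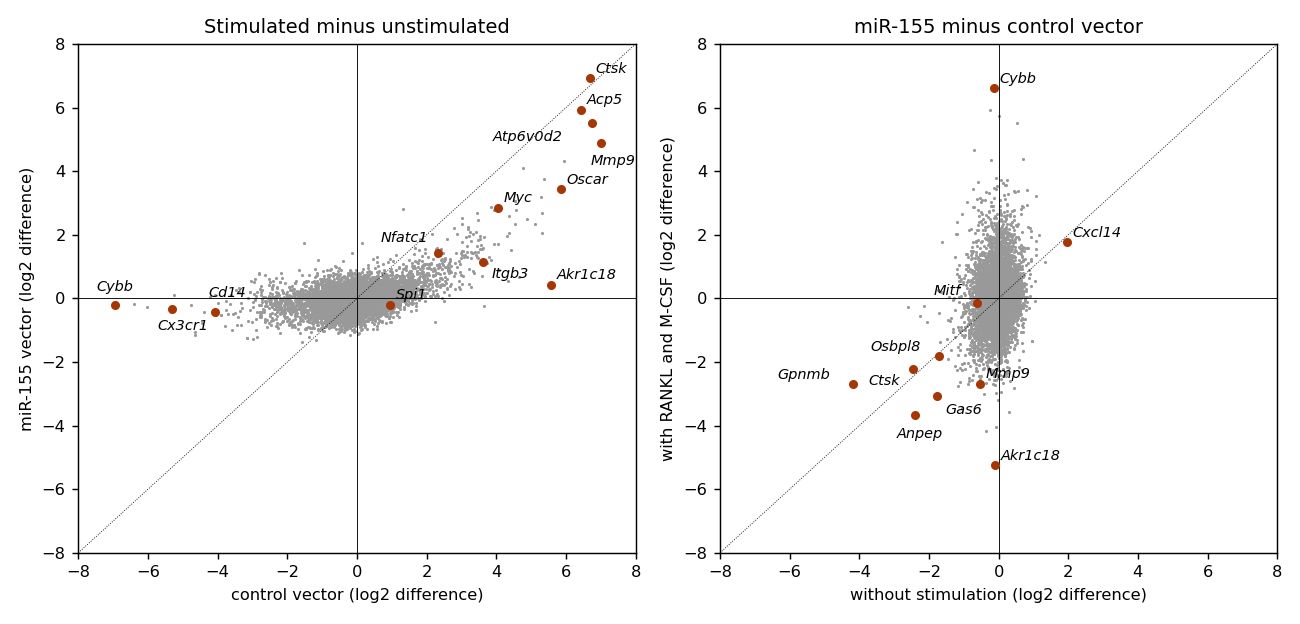
Log2 differences of 13561 genes (grey points, named genes in red, dotted line at equal values): stimulated minus unstimulated in miR-155 against control cells (left), and miR-155 minus control vector with stimulation against without (right). On the left Ctsk lies near the dotted line at 6.68 and 6.92, and Cybb lies at -6.95 and -0.21.

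Among genes past 2-fold in both vectors, those with the highest mean response were Ctsk, Acp5, Atp6v0d2, Mmp9, Scin, Oscar, Serpinb6b, Slc9b2, Ocstamp and Ccr1. Scin, an actin-severing protein, lay below the floor without stimulation and was at least 56.6-fold higher in control and at least 16.2-fold higher in miR-155 cells. The immunoreceptor Oscar was higher by 5.85 and 3.43, the protease inhibitor Serpinb6b by 5.38 and 3.75 and the sodium-proton exchanger Slc9b2 by 4.78 and 4.11. The chemokine receptor Ccr1 lay below the floor without stimulation and was higher by at least 4.64 and 1.62 (log2); with its values set to the floor Dcstamp took its place among the 10. The 10 lowest genes included the nucleotide receptor P2ry6 (-4.64 and -1.15), the complement C5a receptor C5ar1, at least 16.4-fold lower in control cells and -1.05 in miR-155 cells, Igfbp4 (-3.17 and -1.25), Them6 (-3.15 and -1.24), Sdc3 (-2.99 and -1.29) and Lgals9 (-2.86 and -1.22). Adap1 (-2.21 and -1.09), Irf7 (-1.57 and -1.37), Tfap4 (-1.64 and -1.10) and the myeloid factor Cebpa (-1.38 and -1.20) completed them.

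An additive limma model over all 4 arrays, in which the disagreement between the vectors supplies the error, tested stimulation over both vectors. It called no gene over all 13561 genes, with 1020 at an unadjusted p under 0.05 (540 higher, 480 lower). The lowest adjusted p-values by limma were 0.0595 for Ctsk (log2 6.80, SE 0.20) and 0.0736 for Acp5 (6.18, SE 0.23), both higher in 2 of 2 vectors. With the arrays centred or quantile normalised again, or with an intensity trend, limma called these 2 genes. Adjusted over the list alone, 18 of the 27 osteoclast markers rose, against 0 adjusted over all genes, among them Ctsk (adjusted p 0.00012), Acp5 (0.00015), Mmp9 (0.0031) and Oscar (0.0053) by limma. So did 10 of 17 V-ATPase subunits, 4 of 23 osteoclast transcription factors (Jdp2, Myc, Nfatc1 and Id2), 4 of 18 cell fusion genes, 3 of 20 inflammatory genes (Il1rn, Ccl3 and Ccl9) and Cd83 alone of 11 MHC class II and dendritic cell markers, each with 0 over all genes. The inflammatory list kept calls in only 6 of 7 alternatives. The other 17 lists had 0 calls adjusted over the list alone in this setting; of 7 alternatives, 5 called RANK and M-CSF signalling genes, 5 iron and heme genes, 4 sealing zone and actin genes and 3 interferon-stimulated genes. These include the macrophage and both cell cycle lists, whose responses differed most between the vectors. Lists share members, Atp6v0d2 being in 3 of them.

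Without stimulation the vectors differed little, and mostly by lower expression in miR-155 cells. Of 83 genes past 2-fold, 74 were lower and 9 higher. Gpnmb, a lysosomal and melanosomal glycoprotein, was 18.1-fold lower (-4.18). Ctsk (-2.45) lay at 6.72 in control cells and at 4.26, next to the floor, in miR-155 cells. The aminopeptidase Anpep was at -2.41. The proton pump list had a median of -0.28, with 5 of 17 subunits at least 1.5-fold lower and none higher, led by Atp6v0d2 (-0.97) and Atp6v1a (-0.83). Lysosome genes had a median of -0.25, with 3 of 27 lower, such as the galactosidase Gla (-1.17). No more than 1 of 10000 random lists had a median as low as either. Macrophage markers (-0.14) lay at the 1.13 percentile, with Mpeg1 at -1.19 and Tlr4 at -1.07, and RANK and M-CSF signalling genes (-0.13) at the 2.03 percentile, with the autophagy adaptor Sqstm1 at -0.65. G1/S genes (0.16), interferon-stimulated genes (0.23) and osteoclast transcription factors (0.17) lay above the 99 percentile, cholesterol biosynthesis (0.12) and oxidative phosphorylation (0.12) genes also above the middle 95%. RANK and M-CSF signalling, the osteoclast transcription factors and oxidative phosphorylation fell back inside that range in at least 1 alternative, the other 6 lists in none.

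Osteoclast markers as a list did not stand apart without stimulation (-0.06, the 13.0 percentile). Nor did cell fusion (-0.00), sealing zone and actin (-0.03), inflammatory (0.07), MHC class II and dendritic cell (0.02), G2/M (0.05), p53 target (-0.17), glycolysis (-0.12), iron and heme (-0.11) and stress response genes (-0.07), nor T and B cell (-0.03), fibroblast and osteoblast (-0.03) and granulocyte and mast cell markers (0.19). The reported miR-155 targets had a median of -0.07, the 8.88 percentile, with 4 of 46 at least 1.5-fold lower and none higher. Those 4 were Hbp1 (-1.10), Trp53inp1 (-0.70), Mitf (-0.63) and Rheb (-0.62). Bach1 was at -0.57, Spi1 at 0.10, Fos at 0.53, Socs1 at 0.27, Inpp5d at -0.01, Cebpb at 0.18 and Csf1r at 0.18. Mitf has 2 probe sets, and the other lay below the floor on all arrays. The Mir155 probe set lay below the floor on all 4 arrays, at 3.58 to 3.73, as did Ifnb1. This assay does not read the mature microRNA, so these arrays do not check the vector.

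With stimulation the vectors differed widely, with 1512 genes past 2-fold, 759 higher and 753 lower in miR-155 cells. This comparison shares the stimulated control array with the stimulation comparison in control cells, so its lists mirror that comparison in part. Osteoclast markers were lower by a median of -1.73, with 26 of 27 at least 1.5-fold lower and Adam8 higher (0.61). Mmp14 (-3.58), Mmp9 (-2.68), Oscar (-2.56) and Itgb3 (-2.49) were the lowest. V-ATPase subunits had a median of -1.30 (15 of 17 lower), osteoclast transcription factors -0.72 (15 of 23 lower, 2 higher), with Prdm1 at -2.81, Fos at -1.30, Spi1 at -1.05 and Nfatc1 at -0.94, and Mitf at -0.13. G2/M genes (2.30, all 29 at least 1.5-fold higher), G1/S genes (1.84), macrophage markers (1.69, 15 of 22 higher and 1 lower) and interferon-stimulated genes (0.62) were higher, Mki67 by 2.91 and Cybb by 6.61. Lower lists below the 2.5 percentile were lysosome (-0.50), cell fusion (-0.57), sealing zone and actin (-0.46), RANK and M-CSF signalling (-0.46), inflammatory (-0.40), MHC class II and dendritic cell (-0.37), p53 target (-0.45), oxidative phosphorylation (-0.44) and iron and heme genes (-0.58). Without a filter on low values the inflammatory and the MHC class II and dendritic cell lists fell back inside the range of random lists.

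Cholesterol biosynthesis (-0.30), glycolysis (-0.02), stress response (-0.08), T and B cell (-0.10), fibroblast and osteoblast (0.06) and granulocyte and mast cell lists (0.01) did not stand apart between the stimulated vectors. The reported miR-155 targets had a median of -0.01, the 54.7 percentile, with 9 of 46 at least 1.5-fold lower and 7 higher. The plot of list medians sets all lists beside the range of random lists.

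**Figure D3:**
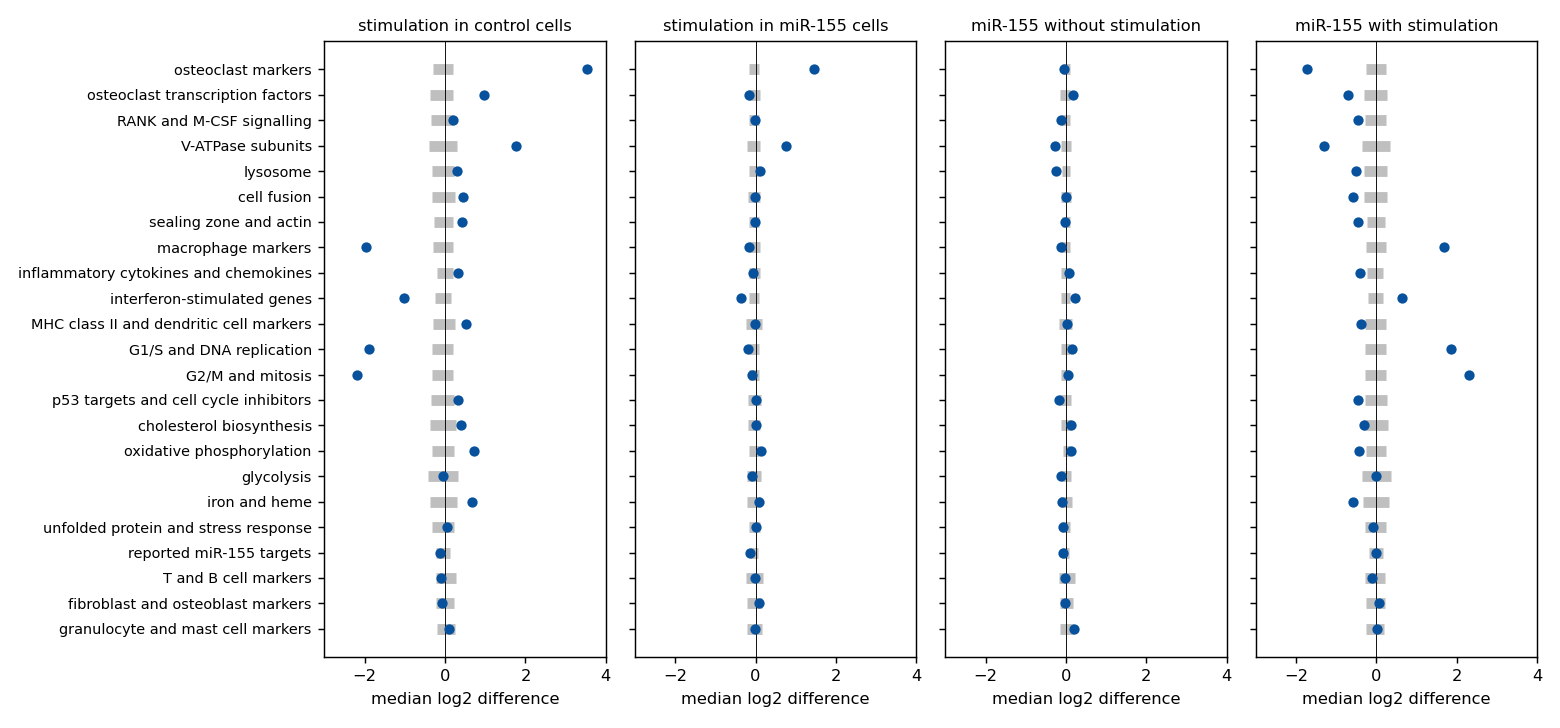
Median log2 difference of the 23 gene lists in the 4 comparisons between arrays, as points over members above the floor, where grey bars span the middle 95% of 10000 random lists matched on expression. Osteoclast markers stand at 3.53, 1.45, -0.06 and -1.73 from left to right, and G2/M genes at -2.18, -0.09, 0.05 and 2.30.

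Differences between the vectors that held in both states were mostly toward lower expression in miR-155 cells, with 165 genes at least 1.5-fold lower and 64 higher in both. The lowest, without and with stimulation, were Gpnmb (-4.18 and -2.70), Anpep (-2.41 and -3.67), Gas6 (-1.78 and -3.08), Ctsk (-2.45 and -2.22), Edil3 (-1.05 and -3.43), Il1rn (-1.17 and -2.75), Rgs1 (at least 1.71-fold lower and -2.63), Layn (-0.87 and -2.68), Osbpl8 (-1.72 and -1.82) and the urokinase gene Plau (-0.84 and -2.61). The highest were Themis2 (0.69 and at least 19.4-fold), Gpr84 (0.82 and 3.42), Il18rap (1.07 and at least 3.68-fold), the chemokine Cxcl14 (1.95 and 1.76), the Fc receptor Fcgr1 (0.67 and 2.90), the gap junction gene Gja1 (1.16 and at least 3.31-fold) and the histone genes H2ac4 (0.83 and 2.92), H4c4 (0.69 and 2.87), H4c6 (0.65 and 2.80) and H2bc3 (0.64 and 2.65). Themis2, Il18rap and Gja1 lay below the floor in the stimulated control cells and Rgs1 in the unstimulated miR-155 cells. With such values set to the floor, Il18rap, Gja1 and Rgs1 no longer ranked among the 10. Histone genes belong to families of near-identical copies, so their separate values are uncertain. Of the genes past 2-fold without stimulation, 7 of 9 higher and 27 of 74 lower ones were past 2-fold the same way with stimulation, against 0.504 and 4.11 for independent lists. The differences correlated across genes with a Pearson r of 0.14 and a Spearman rho of 0.11. The additive limma model called 0 genes for miR-155 over both states, with a lowest limma adjusted p of 0.889. It had 524 genes at an unadjusted p under 0.05, fewer than that threshold alone would give over 13561 genes with no effect. Adjusted over the list alone it called Ctsk among the osteoclast markers (log2 -2.33, SE 0.20, limma adjusted p 0.0083, lower in 2 of 2 states), and no member of the other 22 lists in this setting. Inflammatory genes had calls for miR-155 in 5 of 7 alternatives, up to 5 genes, so their 0 depends on the processing.

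The response to stimulation differed between the vectors by a factor above 2 for 1528 genes, higher in miR-155 cells for 899 and lower for 629. This difference uses all 4 arrays and was not tested. Macrophage genes were highest, Cybb at 6.74, Lyz1 at 6.20, Lyz2 at 5.74 and Cx3cr1 at 4.99, with Tlr7. In control cells Tlr7, an endosomal RNA sensor, was at least 19.7-fold lower with stimulation, against a difference of 0.10 in miR-155 cells. The steroid dehydrogenase gene Akr1c18, Cd200, Mmp14 (-3.89), the metallothionein Mt3 (-3.80) and Prdm1 were lowest. Akr1c18, Cd200, Prdm1 and Tlr7 have values below the floor; with these set to the floor their differences were -4.84, -4.05, -2.95 and 4.41, and Prdm1 no longer ranked among the 5 lowest. Akr1c18 was at least 28.7-fold higher with stimulation in control cells and stayed below the floor in both miR-155 arrays. By list, the response differed by -1.48 for osteoclast markers, -1.03 for V-ATPase subunits, 2.05 for macrophage markers, 1.71 for G1/S genes and 2.31 for G2/M genes.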

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

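The tests of a label swap, of a mixture of cells and of directions at equal intensity, the check of what normalization leaves of a bias, and the counts with values set to the floor were chosen after the results were seen; the share of variance explained by expression bins was planned. With 1 array per group, none of the differences in sign given here was tested.

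Among genes past 2-fold in both stimulation comparisons, 2 went opposite ways. Hmgn5 stood at -1.52 in control and 1.74 in miR-155 cells, and Hpgds, a prostaglandin synthase, at -1.13 and 1.21. Between the vectors, 7 genes were past 2-fold in opposite directions without and with stimulation. Atrx, Clec10a, Gda, Hmgn5, Igf1, Mpeg1 and Pmp22 were all lower in miR-155 cells without stimulation, by -1.04 (Igf1) to -1.61 (Gda), and higher with it, by up to 2.66 (Igf1). Clec10a and Gda lay below the floor in stimulated control cells; with such values set to the floor, Clec10a was no longer past 2-fold with stimulation and 6 genes were left. These genes were named after their values were seen, because the counts are small.

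Some named genes and lists also changed sign between the states in the comparison of miR-155 with control cells. Without and then with stimulation, Fos stood at 0.53 and -1.30, Ocstamp at 0.68 and -1.42, Prdm1 at 0.45 and -2.81, Tnfrsf11a at 0.38 and -0.73, Sdc3 at -0.66 and 1.04 and Tlr7 at -0.70 and 4.67. Prdm1 without stimulation and Tlr7 with it have 1 value below the floor: against the floor they stood at 0.14, inside the noise reference of 0.37, and 3.70, so a change of sign is not shown for Prdm1. Tnfrsf11a without stimulation lay barely past that reference (0.376 against 0.370). The osteoclast transcription factors stood at 0.17 and -0.72, the macrophage markers at -0.14 and 1.69 and the oxidative phosphorylation genes at 0.12 and -0.44. The values without stimulation of the first and last of these lists fell back inside the range of random lists in at least 1 alternative.

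Probe sets outside the gene-level comparisons also differed. Of 6472 probe sets with no symbol and a value above the floor, 908 were past 2-fold with stimulation in control cells, 510 with stimulation in miR-155 cells, 409 between the unstimulated vectors and 829 between the stimulated vectors. Of 905 probe sets with several symbols, 139 were past 2-fold with stimulation in control cells. Their identity was not analysed here.

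The pattern that most calls for a second look is the smaller response of miR-155 cells, where 142 of the 777 higher and 12 of the 939 lower genes of control cells were past 2-fold the same way; by count at 1.5-fold, 465 against 1673 genes were higher and 506 against 2053 lower, so the difference between the sides depends on the threshold. Whether vector labels were swapped in 1 of the 2 states cannot be decided. Of the 83 genes past 2-fold without stimulation, 69.9% (58 genes, exact 95% interval 58.8 to 79.5%) differed the same way with it. A swap would put that share under 50% only if the vector shifts genes the same way in both states, which was not tested. A bias of the stimulated control array that depends on intensity alone, with no real change, is argued against. Such a bias would move genes of equal intensity the same way. Of the 1716 genes past 2-fold, 31.6% (542 genes, exact interval 29.4 to 33.8%) went against the more frequent direction in their intensity bin. That 0 of 4649 did under a simulated bias follows from how it was built. A bias beside real changes is not addressed. The share of variance explained by 10 bins (0.548%) decides nothing. An added bias that raised it to 75.3% left 0.690% after quantile normalization. The exact intervals in this paragraph treat genes as independent and do not measure the spread between cultures. A single fraction of fully responding cells in the stimulated miR-155 culture stays open. Genes induced at least 4-fold in control cells numbered 222. For 68 of them (30.6%, exact interval 24.6 to 37.1%), the level lay beyond the noise reference from what 1 common fraction of 0.163 gives. Noise of that size alone would put 5% there. The share is above the bound of 10% for a pure mixture, but its interval spans the opposing bound of 30%. The rule that the interval must clear the bound was added after the value was seen. The noise reference describes dim probe sets and is no replicate error, so the excess over 5% does not settle the question. An effect of miR-155 on differentiation, swapped labels, a culture that responded less for another reason, and a fault of 1 array cannot be told apart. There is 1 culture per group, and no biological explanation was tested.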

How the results depend on the processing

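The removal of the median of each expression bin and the setting of values below the floor to the floor were chosen after the data were examined; the other alternatives were planned. Over the alternatives, 49 counts and correlations stayed within their bounds and 19 moved. Renewed quantile normalization, median centring and the mean over probe sets gave 960 values for the preset genes and those named as highest or lowest. All stayed within the noise reference. Genes named only as list members, or added later, were not included. With values set to the floor, 15 of 310 values of those preset, highest or lowest genes above the floor moved past the noise reference. They lay in Akr1c18, C5ar1, Ccr1, Cd200, Il18rap and Tlr7. Other genes named here were not counted, and among them Il7r and Gda also moved past it. No direction of the correlations, list medians or preset, highest or lowest genes beyond its reference reversed under the alternatives set beforehand. The osteoclast transcription factors in miR-155 cells, inside the range of random lists, changed sign between median and mean. Judged by the distance from the middle to the edge of the range of random lists, 547 values of list medians stayed and 28 moved; of 62 lists outside that range, counted per comparison, 51 lay outside it in every alternative, including 6 of 9 for miR-155 without stimulation (osteoclast transcription factors, RANK and M-CSF signalling and oxidative phosphorylation did not). Values set to the floor gave totals past 2-fold of 1686, 178, 80, 1487 and 1497 in the order used below. The counts past 2-fold moved by over 1.5 times only with the threshold. At 1.5-fold the totals were 3726 (stimulation, control), 971 (stimulation, miR-155), 586 (miR-155, unstimulated), 3512 (miR-155, stimulated) and 3846 (difference of the responses), and at 3-fold 769, 54, 15, 557 and 557. limma called 2 genes for stimulation (Acp5 and Ctsk) with renewed quantile normalization, with median centring and with an intensity trend. With the mean over probe sets it called 1 (Ctsk). It called 0 in the planned setting and with no filter, a stricter filter or robust variances. An added 2-fold limit can only remove calls, so its 0 was fixed by the planned setting. The lowest adjusted p by limma ranged from 0.0259 to 0.0818 over the alternatives. The correlation of the stimulation responses was 0.437 without a filter, 0.278 by rank and 0.686 over genes past 2-fold in either vector; that of the miR-155 differences was 0.113 by rank and 0.258 over genes past 2-fold in either state. Genes past 2-fold were chosen on the same differences that are correlated, so 0.686 and 0.258 are no independent check of the correlations over all genes. The cause of the other shifts was not tested. List medians moved by more than the noise reference of single probe sets, a wide bound for a list, with the mean in place of the median for osteoclast markers (1.92) and osteoclast transcription factors (0.34) in miR-155 cells and for cell fusion in control (1.13) and miR-155 cells (0.66), and without a filter for macrophage markers in the 3 comparisons that use the stimulated control array (-1.19, 0.89 and 1.34), where genes below the floor enter. Calls adjusted over the list alone ranged over 7 alternatives from 18 to 19 for osteoclast markers, 10 to 15 for V-ATPase subunits, 4 to 8 for osteoclast transcription factors, 3 to 4 for cell fusion and 0 to 5 for inflammatory genes, and reached 2 for RANK and M-CSF signalling, 5 for sealing zone and actin, 3 for interferon-stimulated and 3 for iron and heme genes, which had 0 in the planned setting. For miR-155, alternatives reached 6 V-ATPase subunits, 5 inflammatory genes, 1 cell fusion and 1 iron and heme gene. Scaling moved the median of all genes by at most 0.063 (log2). No array could be left out, because each group has 1 and the additive model would keep no residual. The vector term of the additive limma model already sets stimulation within each vector; nothing in the labels pairs cultures further. The seed-site comparison and its alternatives were not run. Genes near the floor, such as Ctsk in unstimulated miR-155 cells, have differences limited by background.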

Other observations

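Some genes of the amino acid and unfolded protein response were lower in unstimulated miR-155 cells although their list did not stand apart (median -0.07). Of its 22 members 5 were at least 1.5-fold lower and none higher, led by the cystine transporter Slc7a11 (-1.45), Trib3 (-0.98), Atf3 (-0.91) and Sesn2 (-0.83). The chemokine Ccl3 stood at -1.30. Ccl2 and Il7r, a receptor chain counted here among T and B cell markers, lay below the floor in these cells and were at least 2.32-fold and at least 1.47-fold lower. Cxcl10, an interferon-induced chemokine, was higher (0.94).

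The test of spontaneous differentiation in this paragraph was chosen after the list values were seen; the targets of the Mitf family were listed before their own test, but after the leading genes of the comparison had been seen. The lysosome and V-ATPase lists, which share 0 genes, were both lower in unstimulated miR-155 cells (-0.25 and -0.28). Whether less spontaneous osteoclast differentiation explains the lower lysosome median cannot be decided. Scaled by the stimulation responses of the 2 lists, the V-ATPase shift predicts -0.046 for lysosome genes. The observed median lay -0.205 from that value, beyond the 0.0996 that random lists allow. The scaling rests on a lysosome response that split in control cells (12 of 27 higher, 8 lower) and carries no error of its own. Osteoclast markers as a list did not stand apart between the unstimulated vectors (-0.06, the 13.0 percentile). Of these 27 markers, 5 were at least 1.5-fold lower, among them Ctsk (-2.45) and Atp6v0d2 (-0.97), and 1 was higher (Ocstamp, 0.68). The list as a whole thus does not point to less differentiation, while single markers do. Lower activity of the Mitf family, transcription factors that drive lysosomal genes, is a candidate explanation. Outside the lysosome and V-ATPase lists, 24 further target genes above the floor had a median of -0.11. This lay at the 2.21 percentile of random lists, just past the 2.5 set for the test. Of these 24, 3 were at least 1.5-fold lower (among them Fnip1 at -0.99 and Flcn at -0.70), 1 at least 1.5-fold higher (Rab27a at 0.64) and 7 above 0. Of the 31 genes listed, 2 are also osteoclast markers. The family members Mitf (-0.63) and Tfec (-1.39) were lower, while Tfeb (0.21) and Tfe3 (0.11) were not. Between the stimulated vectors the 24 targets had a lower median of -0.46, at the 0.01 percentile, while Mitf stood at -0.13. The shift of the targets is thus not particular to unstimulated cells and did not follow the Mitf level. All of these shifts come from 1 array per group, so lower Mitf family activity remains a hypothesis.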
